A study of Saccharomyces cerevisiae with 25 samples.

How the data were processed

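Total RNA was sequenced from 1 time course of a Saccharomyces cerevisiae strain in the BY4741 background that carries a yellow fluorescent protein under the PHO84 promoter and is labelled as lacking PHM3. PHM3 is an older name of VTC4, the polymerase subunit of the vacuolar complex that makes polyphosphate. Per the labels' protocols, cells grown with high phosphate were washed and moved to medium without phosphate, RNA was extracted with a 96-well kit, and cDNA was sequenced on an Illumina HiSeq instrument. There were 25 libraries: 1 from high phosphate at 0 min and 24 taken every 15 min from 15 to 360 min. No time point had a replicate.

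Reads were aligned with Bowtie to the R64 build, per the submitters' processing notes. The Bowtie version, the gene annotation, the counting tool and any filter are not given in the sources used here. The deposited values are log2 RPM, that is, log2 of reads per 1000000 listed reads, as their sums show. With 2 raised to each listed value, the sums per library lay between 999809 and about 1000000. They are not ratios to the first time point, although the series text describes such a normalization. The smallest listed value of each library equals 10 steps of the spacing between low values, so genes with fewer than 10 reads have no value. Between 93.5% and 95.4% of the listed values of a library were whole numbers of reads, within 0.02 reads. The rest were fractions, as they would be if reads shared by similar genes were divided among them. Which ribosomal protein genes held fractions was not examined, so their values are not known to be independent of each other. PHO11, PHO12 and PHO5 were whole reads in 1, 2 and 3 of 25 libraries, and VTC1, VTC2, VTC3, VTC4 and PHO84 in 25 of 25, so the values of PHO5, PHO11 and PHO12, though tested and counted as 3 genes, are not known to be independent of each other.

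The depth implied by this spacing ran from 106672 reads at 195 min to 1911747 at 105 min, with a median of 746734. The 195 min and 345 min libraries were shallow (106672 and 188278 reads, with 2360 and 3595 listed genes). The others held at least 501479 reads and 4571 listed genes. Intervals and limits of differences cover counting and spread between libraries only. Of 6701 rows, 51 had no gene name and held no value, and 2 shared a name and were left out. Of the 6648 names left, 1072 had no value in any library, 2205 had one in all 25, and 5962 were matched to the R64 annotation, which supplied the coordinates. These span the annotated gene, introns included.

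The no phosphate libraries were grouped into windows of 8 neighbouring time points: 15 to 120 min, 135 to 240 min and 255 to 360 min. Log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with high phosphate and the 3 windows as levels, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A gene was tested if it was listed in at least 6 of 8 libraries of each window and, against high phosphate, at 0 min. For 15 to 45 min against 60 to 120 min, the first window was split, with at least 2 of 3 and 4 of 5 libraries listed. The single high phosphate library is assumed to vary like the others around their window means. The labels do not say that time points came from separate cultures, and neighbours in time are not independent, so p-values measure only the spread between these libraries. Real change within a window also widens that spread. A moderated F test of a natural cubic spline of time with 4 degrees of freedom covered the 24 no phosphate libraries.

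Gene lists, 32 in all, were fixed before the data were examined: the PHO regulon (Pho4-driven phosphate starvation genes, VTC4 left out), PHO signalling, ribosomal proteins, ribosome biogenesis, RNA polymerase I and III, translation factors, general stress, Hsf1 chaperones, unfolded protein response, 4 cell cycle lists (G1/S, histones, G2/M, M/G1 daughter-cell genes), glycolysis, hexose transporters, glucose-repressed genes, TCA cycle, respiratory chain, mitochondrial ribosome, amino acid, purine, phospholipid and ergosterol synthesis, sulfur assimilation, iron and zinc regulons, nitrogen catabolite genes, autophagy, proteasome, and markers of MATa cells, MAT alpha cells and sporulation. Lists with at least 4 tested members were compared with all other genes by the pre-ranked form of camera in limma on the moderated statistics, with a preset correlation between genes of 0.01, because camera itself takes no missing values. Adjustment was over lists within a comparison. The alternative with a correlation estimated per list used residuals with missing values filled by fitted values. The time to 0.5 of a list's largest response was read from its mean profile against 0 min after a running median of 3 points, with linear interpolation, for lists whose largest mean was at least 0.5. Its interval came from 1000 resamplings of the list's members and covers the spread between genes only.

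Genes were named by a rule set before the data were examined. In each comparison it took the 10 largest rises and 10 largest falls among genes with a standard name that passed the test and whose values did not overlap between the windows, or lay on 1 side of high phosphate at every time point. It also took VTC4, PHO84, PHO5, PHO4, the PHO regulon, HIS3, LEU2, MET17, URA3, and up to 4 members of each list described. Differences are log2, with the standard error (SE) of the fit.

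The fit was tested on simulated values that kept the mean, spread and missing values of each real gene, with 200 changed genes. Values were drawn independently for each gene and library. They held no correlation between genes or neighbouring times and no shift of whole libraries. The shares and false calls below describe such values and may not hold for the real libraries. For 255 to 360 min against 15 to 120 min it recovered 28.4%, 88.1% and 100% of changes of 0.5, 1 and 2 (log2), with 7 false calls among 4634 genes. For 15 to 120 min against high phosphate it recovered 0%, 11.9% and 84.8%, with 3 false calls among 4613 genes. For 255 to 360 min against high phosphate the shares were 1.5%, 17.9% and 84.8%, with 1 false call among 4613. For 15 to 45 min against 60 to 120 min they were 14.9%, 65.7% and 97.0%, with 4 false calls among 4555. Alternatives to the scaling, windows, filters, variance model, pseudocount and the libraries used were run. Other steps used Python with numpy, pandas and scipy.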

Results

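The series followed the transcriptome of 1 yeast strain through 360 min without phosphate. It comprised 1 library from high phosphate at 0 min and 24 libraries without phosphate, taken every 15 min. Depth ran from 106672 to 1911747 reads per library, and the 2 shallowest were at 195 and 345 min. Because values are shares of the reads of a library, the fall of very abundant transcripts raises all others. The median tested gene stood 0.42 (log2) higher at 255 to 360 min than at 0 min and 0.22 higher at 15 to 120 min. The median difference between these windows was 0.23.

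VTC4 (chromosome X, 411234 to 413399, R64), the gene the strain is labelled as lacking, had reads in all 25 libraries. Its level was 8.04 ± 0.24 log2 RPM (reads per 1000000 listed reads; SD, n = 25 libraries), or 7.92 at 0 min. It had between 50 and 517 reads per library. The libraries are therefore called "labelled phm3_del" here, and the directions below belong to the libraries under that label. The labels do not say which part of the gene was removed, and the table holds no read positions, so a part left in place would not be seen. VTC4 did not differ detectably from high phosphate at 255 to 360 min (difference 0.12, SE 0.30, adjusted p = 0.79), with a 95% interval from -0.46 to 0.70. This difference was -0.46 with libraries centred on their median. VTC1, VTC2 and VTC3, genes for other subunits of the complex, rose in the same libraries. The rises were 2.80 (SE 0.27), 1.59 (SE 0.27) and 3.05 (SE 0.27). Of the auxotrophic loci of the strain background, HIS3, LEU2 and MET17 were listed in no library, and URA3 in 1, at 105 min. Because 1072 names had no value in any library, this absence alone does not establish the background.

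**Figure D1:**
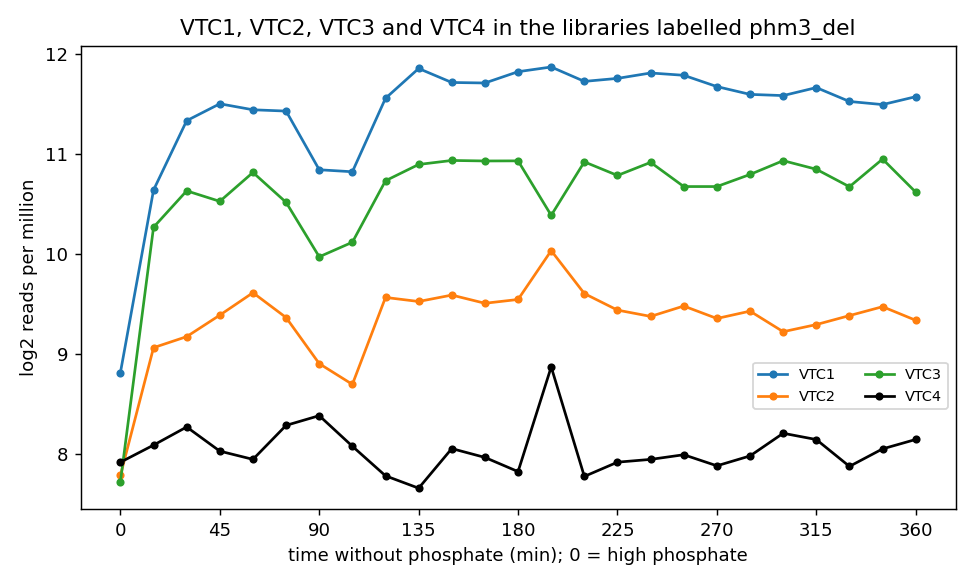
Levels of VTC1, VTC2, VTC3 and VTC4 (vertical axis, log2 RPM) against time without phosphate (horizontal axis, min), 1 point per library labelled phm3_del. VTC4 stays between 7.66 and 8.87, with its highest value in the shallow 195 min library, where it rests on 50 reads.

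The comparison of 255 to 360 min with high phosphate asks what had changed late in the course. No library after 0 min had phosphate. In either comparison with high phosphate, starvation cannot be told apart from the wash, the new medium or further time in culture. Phosphate genes and stress genes rose, and the ribosomal protein genes fell. All 17 tested PHO regulon genes rose, by a mean of 3.09 ± 0.92 (SD between genes), over all genes and adjusted over the list alone, and against other genes (adjusted p = 5.59e-18, and adjusted p = 0.0377 with an estimated correlation). The repressible acid phosphatase gene PHO5 (chromosome II, 429548 to 430951) rose 21.2-fold (difference 4.41, SE 0.46, adjusted p = 1.3e-07). The high-affinity phosphate transporter gene PHO84 (chromosome XIII, 24037 to 25800) rose 14.4-fold (3.85, SE 0.28). SPL2, an inhibitor of low-affinity phosphate uptake, rose 14.8-fold (3.89, SE 0.31). GIT1, a glycerophosphoinositol transporter gene, was not listed at 0 min and reached 6.19 ± 0.28 (SD, n = 8). This was at least 10.7-fold above the listing limit of 10 reads. Of the 20 genes of the PHO regulon list, GIT1, CTF19 and PHM7 were not tested. CTF19 was listed in 0 libraries and PHM7 in 10, at a mean of 4.30 log2 RPM. PHO4, the activator of the regulon, rose by 1.25 (SE 0.35, adjusted p = 0.0078); it did not pass with libraries centred on their median (0.75, adjusted p = 0.127) or on genes listed in all 25 (0.84, adjusted p = 0.0652), where the settings tried gave 0.00476 to 0.127.

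Of 137 ribosomal protein genes, 135 fell, over all genes and adjusted over the list alone, by a list mean of -2.81 ± 0.51 (adjusted p = 4.56e-113, and adjusted p = 0.0135 with an estimated correlation). RPL9A (-3.57, SE 0.57), RPS0B (-3.48, SE 0.63), RPL8A (-3.43, SE 0.62), RPL21A, RPS24B, RPS26B, RPL16A, RPL12A and RPS20 were among the 10 largest falls, with ASC1, a protein of the small subunit (-3.43, SE 0.58). Translation factor genes fell in 15 of 29 cases, and in 18 adjusted over the list alone (adjusted p = 2.04e-14, and adjusted p = 0.0377 with an estimated correlation), led by the elongation factor gene EFT2 (-1.94, SE 0.39). Ribosome biogenesis genes averaged -0.93 ± 0.46, but only 3 of 106 passed and 0 adjusted over the list alone. RNA polymerase I and III genes averaged -0.76 ± 0.51, with 1 of 20 passing and 0 adjusted over the list alone. Both lists lay below other genes, but not with an estimated correlation (adjusted p = 0.502 and adjusted p = 0.516 with an estimated correlation).

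General stress genes, targets of Msn2 and Msn4, rose in 38 of 39 cases, also adjusted over the list alone, by a mean of 3.25 ± 0.97 (adjusted p = 2.71e-15, and adjusted p = 0.274 with an estimated correlation). The small heat shock protein gene HSP26 (chromosome II, 382030 to 382674) rose 39.9-fold (5.32, SE 0.54), GRE1 rose 23.4-fold (4.55, SE 0.55), DDR2 22.1-fold (4.47, SE 0.55), and the catalase gene CTT1 20.9-fold (4.38, SE 0.66). FMP16 (4.60), MSC1 (4.48), the glyceraldehyde-3-phosphate dehydrogenase gene TDH1 (4.41), HPF1 (4.34) and the aromatic aminotransferase gene ARO9 (4.33) completed the 10 largest rises with PHO5. Nitrogen catabolite genes rose in 12 of 14 cases, and in 13 adjusted over the list alone (adjusted p = 0.189 with an estimated correlation), among them the amino acid permease gene GAP1 (3.73, SE 0.57) and the urea transporter gene DUR3 (2.94, SE 0.31). Autophagy genes rose in 14 of 16, the same number adjusted over the list alone (adjusted p = 0.221 with an estimated correlation), led by ATG19 (3.31, SE 0.44). Respiratory chain genes rose in 26 of 30, and in 27 adjusted over the list alone (adjusted p = 0.207 with an estimated correlation). TCA cycle genes rose in 11 of 12, and in 12 adjusted over the list alone (adjusted p = 0.403 with an estimated correlation).

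In this comparison limma found 1154 of 4613 genes higher and 252 lower. The balance rests on the scaling: with each library centred on its median, 389 were higher and 435 lower, and with centring on genes listed in all 25 libraries, 596 and 438. The median centring left the median tested gene at -0.14. It uses the tested genes listed in each library, so the listing limit can move it, unlike centring on genes listed in all 25. With libraries centred on their median the PHO regulon still gave 17 of 17 higher and the ribosomal proteins 135 of 137 lower, but the respiratory chain gave 5 of 30 and the TCA cycle 4 of 12 higher.

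PHO signalling genes rose in 8 of 13 cases, and in 9 adjusted over the list alone (adjusted p = 0.403 with an estimated correlation), with the inositol pyrophosphate kinase genes KCS1 (1.88, SE 0.32) and VIP1 (1.70, SE 0.30) among them. Glycolysis had 7 of 16 higher and 1 lower, the hexokinase gene HXK2 (adjusted p = 0.76 with an estimated correlation). M/G1 daughter-cell genes had 8 of 14 higher (adjusted p = 0.617 with an estimated correlation). Adjusted over the list alone these were 10 and 1 for glycolysis and 9 for M/G1 genes. No other list differed from the rest of the genes by its tested members (adjusted p from 0.178 to 0.989). Their members passing, higher then lower, were 3 and 1 of 20 for Hsf1 chaperones, 2 and 0 of 13 for the unfolded protein response, 1 and 0 of 20 for G1/S, 0 and 0 of 8 for histones. They were 4 and 0 of 15 for G2/M, 1 and 0 of 4 for hexose transporters, and 2 and 0 of 6 for glucose-repressed genes. Members with too few values were not tested. The tests cover 4 of 7 hexose transporter, 6 of 16 glucose-repressed and 10 of 19 iron regulon genes. HXT5, an untested hexose transporter gene, was at least 31.9-fold above the listing limit at 0 min. Further counts were 5 and 0 of 54 for the mitochondrial ribosome, 8 and 4 of 45 for amino acid synthesis and 3 and 3 of 18 for sulfur assimilation. There were 5 and 2 of 17 for purine synthesis, 1 and 0 of 12 for phospholipid synthesis, and 4 and 0 of 25 for ergosterol synthesis. Iron and zinc regulons had 1 of 10 and 1 of 8 higher and 0 lower, and the proteasome 0 of 33 either way. Adjusted over the list alone, 1 unfolded protein response, 3 G2/M, 1 mitochondrial ribosome, 0 iron regulon and 4 sulfur assimilation genes were higher and 2 amino acid synthesis genes lower, and the other counts of these lists were as given. MATa markers had 1 of 6 higher, and the 3 tested sporulation genes 2 higher. Of the MAT alpha markers, which this mating type should not express, MF(ALPHA)1 was listed in 1 library and MF(ALPHA)2 in 0, while STE3 and SAG1 were listed in 22 and 19 libraries at means of 4.85 and 4.34, against 10.7 for the MATa pheromone gene MFA1.

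The comparison of 15 to 120 min with high phosphate asks what changed first. PHO regulon genes rose in 14 of 17 cases, and in 17 adjusted over the list alone, by a mean of 2.35 ± 0.78 (adjusted p = 1.79e-39, and adjusted p = 0.000278 with an estimated correlation). SPL2 rose 13.7-fold (3.78, SE 0.31, adjusted p = 4.05e-09), PHO11 and PHO12, acid phosphatase genes whose values were whole reads in 1 and 2 of 25 libraries, by 3.49 (SE 0.48) and 3.39 (SE 0.45). PHO84 rose 7.16-fold (2.84, SE 0.28), VTC3 by 2.73 (SE 0.27), PHO5 by 2.66 (SE 0.46), and PHM6 by 2.62 (SE 0.42). The sodium-phosphate transporter gene PHO89 rose by 2.58 (SE 0.47) and VTC1 by 2.38 (SE 0.27). ARO9, outside the list, rose by 3.16 (SE 0.45). ARO9 and SPL2 are neighbours on chromosome VIII (375709 to 377250 and 374654 to 375100). PPN1, HOR2 and PHM8 did not pass, with differences of 0.86, 1.92 and 2.12. HOR2 and PHM8 passed when the 15, 90 or 105 min library was left out (adjusted p = 0.0257, 0.0242 and 0.0056 for HOR2, and 0.0423, 0.00608 and 0.0056 for PHM8). PHO4 itself differed by 0.21 (SE 0.35, adjusted p = 0.78), and by -0.04 with libraries centred on their median.

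General stress genes averaged 1.65 ± 0.57 in this window, with 0 of 39 passing over all genes and 31 adjusted over the list alone (adjusted p = 1.21e-13 against other genes, and adjusted p = 0.304 with an estimated correlation). Ribosomal protein genes averaged -0.91 ± 0.26 and ribosome biogenesis genes -0.94 ± 0.31, with 0 of 137 and 0 of 106 passing, also adjusted over the list alone (adjusted p = 0.221 and adjusted p = 0.263 with an estimated correlation). TCA cycle genes averaged 1.10 ± 0.40 (0 of 12 passing, and 5 adjusted over the list alone), nitrogen catabolite genes 1.00 ± 0.51 (1 of 14, and 6 adjusted over the list alone) and autophagy genes 0.87 ± 0.51 (0 of 16, and 5 adjusted over the list alone). All lay above other genes, but not with an estimated correlation (adjusted p = 0.263, adjusted p = 0.263 and adjusted p = 0.32 with an estimated correlation). Iron regulon genes averaged -0.36 ± 0.54, with 0 of 10 passing either way, and lay below other genes (adjusted p = 0.00263, and adjusted p = 0.0188 with an estimated correlation). Glycolysis (mean 0.58, with 1 of 16 higher, and 2 adjusted over the list alone), the respiratory chain (0.58), the mitochondrial ribosome (0.39), RNA polymerase I and III (-0.77) and translation factors (-0.42) also differed from other genes, the last 4 with 0 genes passing either way. None of these 5 lists did so with an estimated correlation (adjusted p = 0.681, adjusted p = 0.32, adjusted p = 0.732, adjusted p = 0.314 and adjusted p = 0.198 with an estimated correlation).

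In total limma found 32 of 4613 genes higher and 0 lower and 647 at an unadjusted p under 0.05. These counts rest on 2 libraries whose profiles lay close to that at 0 min: without the 90 and 105 min libraries, a choice made after seeing the data, 518 genes were higher and 72 lower, with 33 of 39 stress genes higher and 47 of 137 ribosomal protein genes lower. Without the 90 min library alone 87 were higher and 0 lower, and without the 105 min library 118 and 1. With libraries centred on their median 9 were higher, 8 of them PHO regulon genes.

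Single libraries did not change in 1 direction over time. Stress genes stood at a mean of 2.81 ± 0.92 (SD between genes) above 0 min at 45 min, 0.34 ± 0.50 at 90 min, 0.34 ± 0.41 at 105 min and 2.999 ± 0.96 at 135 min. Ribosomal protein genes stood at -1.90 ± 0.50, -0.13 ± 0.29, -0.01 ± 0.17 and -2.33 ± 0.69 at those times, and ribosome biogenesis genes at -2.09 ± 0.67, 0.09 ± 0.24, -0.21 ± 0.25 and -1.89 ± 0.75. The PHO regulon stood at 2.72 ± 0.87, 1.65 ± 0.78, 1.83 ± 0.89 and 3.03 ± 0.90, and all 17 genes stayed above their 0 min value in every library without phosphate. Across the 2205 genes listed in all libraries, which are not independent replicates, Pearson's r with 0 min was 0.726 at 45 min, 0.971 at 90 min, 0.976 at 105 min and 0.671 at 135 min. These are values of single libraries with no test.

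**Figure D2:**
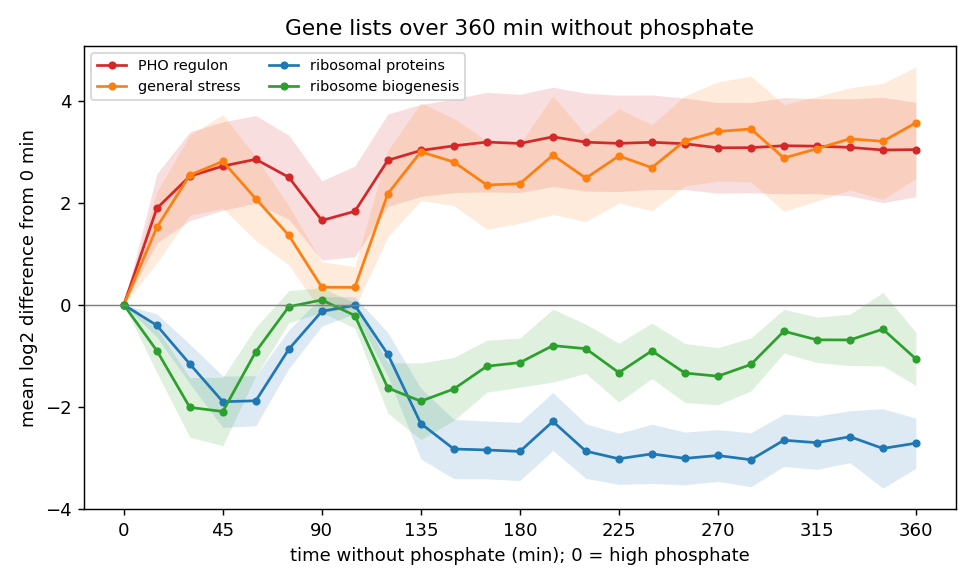
Mean log2 difference from 0 min (vertical axis) of 4 gene lists against time without phosphate (horizontal axis, min); points are single libraries and bands are 1 SD between genes. At 90 and 105 min the stress, ribosomal protein and biogenesis lists lie between -0.21 and 0.34, and the PHO regulon at 1.65 and 1.83.

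**Figure D3:**
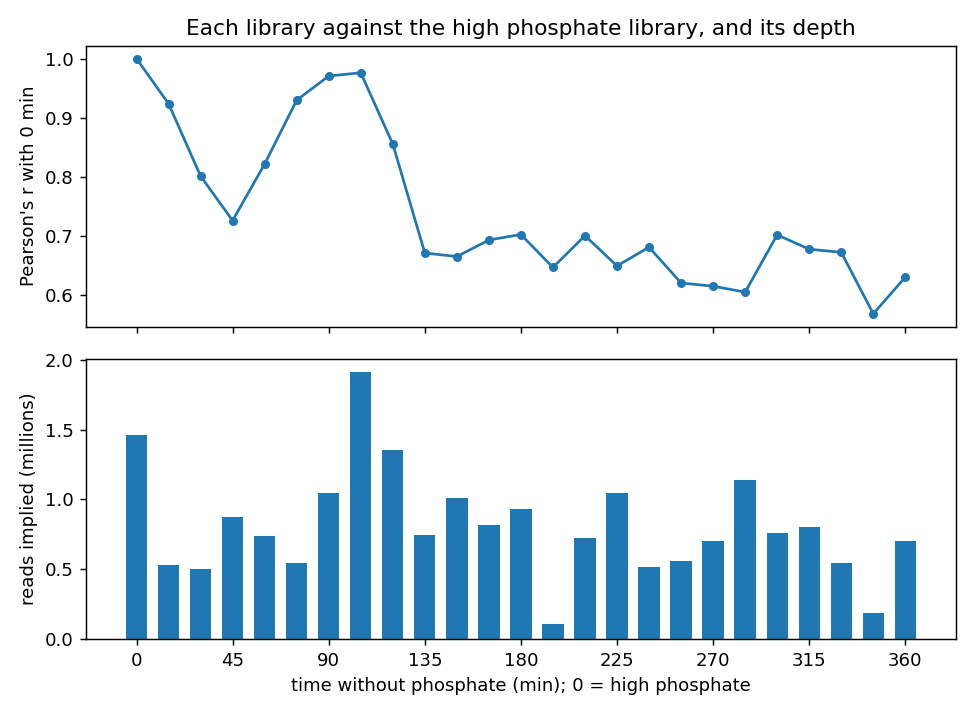
Upper panel: Pearson's r of each library with the 0 min library across 2205 genes, against time without phosphate (min). Lower panel: reads implied per library in units of 1000000, where the 195 and 345 min libraries are the lowest.

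The comparison of 255 to 360 min with 15 to 120 min asks how the late window differs from the early one and does not use the high phosphate library. Ribosomal protein genes fell further in 135 of 137 cases, also adjusted over the list alone, by a mean of -1.89 ± 0.38 (adjusted p = 3.56e-114, and adjusted p = 0.0127 with an estimated correlation). RPS0B (-2.51, SE 0.30), RPL9A (-2.44, SE 0.27), RPS9A (-2.40, SE 0.33), RPS20, RPL24A, RPS4A, RPS6A, RPL21A, RPL8A and ASC1 were the 10 largest falls. General stress genes rose in 34 of 39 cases, and in 35 adjusted over the list alone (adjusted p = 0.528 with an estimated correlation): HSP26 16.5-fold (4.04, SE 0.26, adjusted p = 5.14e-12), GRE1 12.0-fold (3.59, SE 0.26) and the hydrophilin gene SIP18 11.4-fold (3.51, SE 0.25). HPF1 (3.47), FMP16 (3.37), the transketolase gene TKL2 (3.14), DDR2 (3.02), MOH1 (3.02), RRT1 (2.91) and PAI3 (2.88) followed. MOH1 and RRT1 are neighbours on chromosome II (126828 to 127244 and 127299 to 127610).

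Within the PHO regulon, 12 of 17 genes rose further, also adjusted over the list alone (adjusted p = 0.703 with an estimated correlation). The calls of HOR2 and VTC3, among these 12, rest on single libraries. VTC3 did not pass without the 15, 90, 105, 285, 300, 315 or 345 min library (adjusted p from 0.0625 to 0.108). HOR2 did not pass without any 1 of 17 libraries, those at 15, 30, 90, 105, 150 to 180, 210 to 330 and 360 min (adjusted p from 0.051 to 0.122). PHM8, a nucleotidase gene, rose by 1.90 (SE 0.25), PHO5 by 1.75 (SE 0.21), PHO89 by 1.27 (SE 0.22), PHM6 by 1.16 (SE 0.20) and PHO84 by 1.01 (SE 0.13). Few values of PHO5, PHO11 and PHO12 were whole reads (3, 1 and 2 of 25 libraries), so their differences are not known to be independent of each other. SPL2, PHO11, PHO12, PHO86 and VTC2 did not pass, with differences of 0.10, 0.20, 0.14, 0.10 and 0.15 that turn below 0 with libraries centred on their median. Respiratory chain genes rose in 28 of 30 cases, and in 29 adjusted over the list alone (adjusted p = 0.267 with an estimated correlation). Nitrogen catabolite genes rose in 14 of 15, and in all 15 adjusted over the list alone (adjusted p = 0.267 with an estimated correlation). Autophagy genes rose in 14 of 16, also adjusted over the list alone (adjusted p = 0.29 with an estimated correlation). M/G1 daughter-cell genes rose in 12 of 14 cases (adjusted p = 0.267 with an estimated correlation). Translation factor genes fell in 17 of 29, with 18 lower and 1 higher adjusted over the list alone (adjusted p = 0.15 with an estimated correlation). The S-adenosylmethionine synthetase genes SAM1 and SAM2 fell by 1.84 (SE 0.19) and 1.92 (SE 0.31), within a sulfur assimilation list of which 5 of 18 fell and 2 rose (adjusted p = 0.538 with an estimated correlation). PHO signalling genes rose in 10 of 13 cases and fell in 1, also adjusted over the list alone (adjusted p = 0.508 with an estimated correlation). Ribosome biogenesis (2 of 106 higher and 1 lower), G1/S (1 of 20 higher and 2 lower), the mitochondrial ribosome (4 of 54 higher and 7 lower) and the proteasome (1 of 33 higher and 1 lower) lay below other genes with means of 0.02, -0.11, -0.06 and -0.08 (adjusted p = 0.711 each with an estimated correlation). Adjusted over the list alone these were 1 and 1, 1 and 0, 3 and 3, and 0 and 0. Without the 90 and 105 min libraries the shift of ribosome biogenesis genes against other genes was 0.16.

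In this comparison 1462 of 4634 genes were higher and 410 lower. With libraries centred on their median 600 were higher and 840 lower, and with centring on genes listed in all 25 libraries, 976 and 715, so the balance, and with the first its direction, rests on the scaling. The first centring left the median tested gene at -0.07. The F test over the 24 libraries without phosphate found 1459 of 4634 genes changing over time, and 925 with libraries centred on their median.

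The comparison of 15 to 45 min with 60 to 120 min asks for a transient after the wash and the change of medium. Ribosome biogenesis genes were lower in the first 45 min in 34 of 102 cases, and in 90 adjusted over the list alone (adjusted p = 2.64e-40, and adjusted p = 0.182 with an estimated correlation), among them the assembly factor genes YTM1 (-1.85, SE 0.40), NOG2 (-1.68, SE 0.35) and UTP21 (-1.33, SE 0.32). RSA4 (-1.85, SE 0.32) and RRP36 (-1.80, SE 0.39), outside the list, were lower too. RNA polymerase I and III genes were lower in 11 of 20 cases, and in 18 adjusted over the list alone (adjusted p = 0.182 with an estimated correlation). Hsf1 chaperone genes were higher in 5 of 20 cases, and in 13 adjusted over the list alone (adjusted p = 0.182 with an estimated correlation), with BTN2 5.62-fold (2.49, SE 0.36, adjusted p = 0.000741) and CUR1 3.20-fold (1.68, SE 0.33). General stress genes were higher in 8 of 38, and in 27 adjusted over the list alone (adjusted p = 0.436 with an estimated correlation), including HSP42 (2.06, SE 0.44), SPI1 and TPS2. Without the 30 or the 45 min library YTM1, NOG2, UTP21, RRP36, HSP42 and TPS2 did not pass, nor did UTP21 without 75, 90 or 105 min. TMA10 was highest (2.89, SE 0.48). The PHO regulon had 0 of 17 genes passing either way, also adjusted over the list alone, in a comparison for which limma gave 1110 genes at an unadjusted p under 0.05. Ribosomal protein genes averaged -0.38 ± 0.28, with 0 of 137 passing (adjusted p = 2.32e-09 against other genes, and adjusted p = 0.609 with an estimated correlation), and their shift against other genes, -0.46, became 0.13 without the 90 and 105 min libraries, where it passed in the opposite direction (adjusted p = 0.024; from 8.93e-11 to 0.609 over the settings tried). Phospholipid synthesis genes were higher in 5 of 12 cases, also adjusted over the list alone (adjusted p = 0.436 with an estimated correlation). Glucose-repressed genes were higher in 2 of 7, and in 3 adjusted over the list alone (adjusted p = 0.098 with an estimated correlation). Proteasome genes were higher in 1 of 33, and in 14 adjusted over the list alone (adjusted p = 0.484 with an estimated correlation). Sulfur assimilation had 1 of 18 higher, and 4 adjusted over the list alone, autophagy 1 of 15 higher, and 2 adjusted over the list alone, and G1/S 1 of 19 lower either way (adjusted p = 0.484, adjusted p = 0.51 and adjusted p = 0.484 with an estimated correlation). Histones, nitrogen catabolite genes and translation factors had 0 passing either way and differed from other genes with means of -0.44, 0.48 and -0.28 (adjusted p = 0.484 each with an estimated correlation).

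This comparison gave 150 of 4555 genes higher and 111 lower, and it rests on single libraries; the series holds no library from a wash that kept phosphate. Without the 90 and 105 min libraries 2 genes were higher and 0 lower, and a spline of time gave 8 and 2. With libraries centred on their median 116 were higher and 156 lower, and with centring on genes listed in all 25, 205 and 153. Among the scalings tried, only median centring turned the direction of the balance. Leaving out 1 library gave from 8 higher and 1 lower, without 30 min, to 402 and 208 without 60 min, and 395 and 349 without 120 min. Without 15 min it gave 302 and 279, without 45 min 14 and 4, without 75 min 65 and 16, without 90 min 30 and 10, and without 105 min 32 and 14.

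Times to 0.5 of the largest mean response differed between lists. The PHO regulon reached this point at 12.7 min (95% interval over genes 11.2 to 14.6), ribosome biogenesis at 16.4 min (15.5 to 17.2), general stress at 18.9 min (15.3 to 22.6) and ribosomal proteins at 37.2 min (36.4 to 38.2). Hsf1 chaperones (9.31 min, 7.5 to 15.3), sulfur assimilation (10.0 min, 8.09 to 13.04) and the unfolded protein response (10.3 min, 7.86 to 28.8) reached it earlier than the PHO regulon, with overlapping intervals and smaller responses, of at most 1.10. That of the unfolded protein response was 314 min with libraries centred on their median and 51.8 min with no running median. Times under 15 min precede the first library without phosphate and rest on interpolation. G1/S genes reached it at 51.0 min (47.8 to 53.2) and histones at 68.3 min (67.2 to 69.6), but with libraries centred on their median these became 278 and 12.6 min. Without the 90 and 105 min libraries histones gave 165 min.

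**Figure D4:**
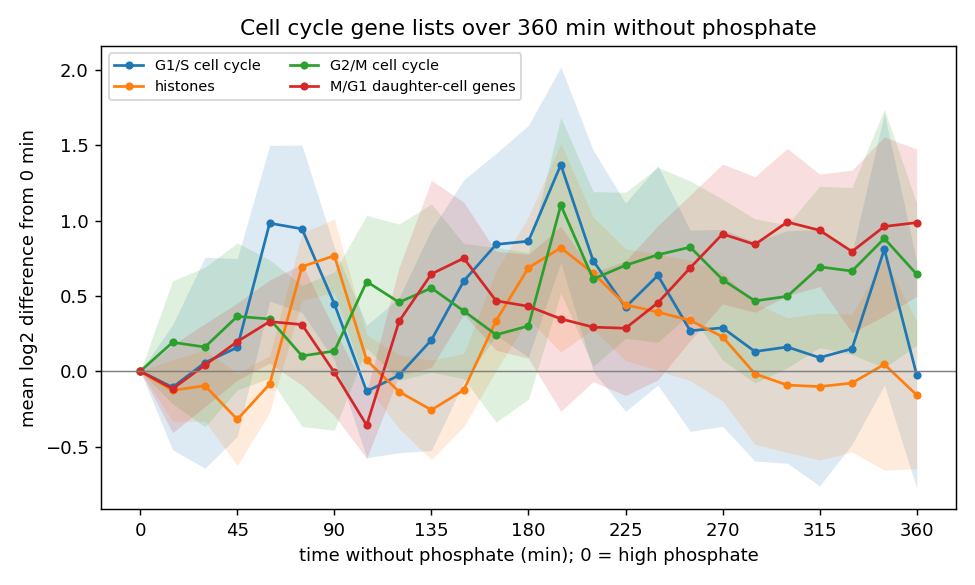
Mean log2 difference from 0 min (vertical axis) of 4 cell cycle lists against time without phosphate (horizontal axis, min); points are single libraries and bands are 1 SD between genes. G1/S genes stand at 0.98 at 60 min and histones at 0.77 at 90 min; at 195 min the means cover 8 of 20 G1/S, 6 of 15 G2/M, 13 of 14 M/G1 and all 8 histone genes.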

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

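The tests of an induced VTC4, of sequence left at its locus, of the 90 and 105 min libraries, of the order of the cell cycle lists and of other splits of the libraries were chosen after the result was seen.

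Single libraries stood apart from the other 7 of their window in 15 of 90 pairs of a list and a window, where chance gives about 1 in 20. Of these 15, 13 were at 195 or 345 min, the shallowest libraries, where low genes are missing. At 195 min the list means against 0 min were 1.04 for the unfolded protein response, 2.73 for glucose-repressed genes, of which 1 member was listed, and 2.12 for autophagy. At 135 min they were 0.86 for glycolysis and 1.31 for the TCA cycle. At 345 min they were 1.44 for PHO signalling, 0.87 for the unfolded protein response, 0.81 for G1/S, 0.75 for glycolysis and -0.33 for hexose transporters. The other means at 345 min were 1.05 for the respiratory chain, 0.75 for the mitochondrial ribosome, 0.19 for phospholipid synthesis, 2.57 for nitrogen catabolite genes and 2.15 for autophagy.

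VTC4 had reads in every library although the strain is labelled as lacking it. Its value was a whole number of reads in 25 of 25 libraries (tolerance 0.02), against 1 of 25 for PHO11, which argues against reads shared with another gene. Its difference from high phosphate at 255 to 360 min was 0.12, with an upper 95% bound of 0.70, under 0.79, which is 0.5 of the smallest difference among VTC1, VTC2 and VTC3, and this argues against an intact gene induced like them. Transcripts of sequence left at the locus remain a possible explanation for the mean level of 8.04 (log2 RPM), because read positions are not in the table. An intact gene that does not respond, from a wrong label, stays open as well.

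The libraries at 90 and 105 min lay close to 0 min in ribosomal protein, ribosome biogenesis and stress genes. In both, 12 of 17 PHO regulon genes were more than 1 (log2) above 0 min, which argues against libraries taken in high phosphate under a wrong label. The library nearest in depth to that at 90 min (1048845 against 1046803 reads), at 225 min, correlated with 0 min at 0.649. This single library argues against depth for the 90 min library only. The 105 min library, the deepest of the series, was not matched. The share of mixed-in high phosphate RNA that each gene would need had an upper quartile over PHO regulon genes of 0.793 at 90 min, against lower quartiles of 0.745 over ribosomal protein, 0.917 over stress and 0.958 over ribosome biogenesis genes, and of 0.727 at 105 min, against 0.884, 0.918 and 0.628. These ranges overlap for ribosomal proteins at 90 min and for ribosome biogenesis at 105 min, and they take the mean of the 60 and 135 min libraries as the unmixed profile, which is an assumption, so mixing was not excluded in either library. A passing recovery of growth genes while phosphate genes stay up may also account for them, and was not tested, since the course was run once.

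Peak times of cell cycle genes between 15 and 120 min correlated weakly with the order G1/S, histones, G2/M, M/G1 across 52 genes (Spearman 0.321, one-sided permutation p = 0.00983). The permutation moves list labels among genes as if genes were independent. Genes of 1 list move together in 1 course, so its p-values overstate the evidence. The median peaks were 67.5, 90, 105 and 75 min, so the first 3 lists followed this order and M/G1 genes, which should come last, did not. Between 135 and 255 min the median peaks were 180, 195, 240 and 150 min, again with only M/G1 genes out of this order, and the correlation did not pass (Spearman -0.0527, one-sided permutation p = 0.654). Partial synchrony of the cells after the transfer may contribute in the first span, which also holds the 90 and 105 min libraries, but stays open.

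For 255 to 360 min against 15 to 120 min, 1 of 100 splits of the 16 libraries gave as many genes, the real split with 1872, and the highest other gave 503. The splits treat libraries as exchangeable, but neighbours in time are not independent, and any slow drift favours the real split. This test therefore cannot exclude a chance drift of the single course as the origin of the count. The windows are ordered in time, so any drift of the culture or of handling with time goes with them. For 15 to 45 min against 60 to 120 min, 7 of 56 splits of the 8 libraries gave as many genes as the real 261, so chance could not be excluded. The highest other split, 75, 90 and 105 min against the rest, gave 1393 genes, several times the real count, which points to a structure of the samples other than this comparison.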

How the results depend on the processing

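The settings without the 90 and 105 min or the 195 and 345 min libraries, with centring on genes listed in all 25 libraries, and with unlisted values set to the listing limit were chosen after seeing the data. DESeq2, planned as an alternative, was not run, because the values are log2 RPM and not counts. Of the settings tried for counts of genes, 294 stayed within 1.5 times and 43 did not. Shifts of lists kept their direction and side of the threshold in 951 cases, lost their call in 75 and turned in 8. Differences of named genes did so in 1505, 66 and 21 cases, and 12 gained a call. The shallow libraries limit what can be said of low genes at 195 and 345 min. The cause of the changes below was not tested. By construction, however, centring moves the median gene, and a stricter filter or threshold leaves fewer genes. Median centring did not remove the shift of the median tested gene exactly. It left this gene at -0.14 for the late window against high phosphate and at -0.07 for the late against the early window.

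For 255 to 360 min against 15 to 120 min (1462 higher and 410 lower), libraries centred on their median gave 600 and 840, centring on genes listed in all 25 gave 976 and 715, a mean of at least 6 gave 900 higher, and a difference of at least 1 gave 359 and 163. Leaving out 1 library gave 1291 to 1544 higher and 362 to 428 lower. For 15 to 120 min against high phosphate (32 and 0), the median centring gave 9 higher, time points averaged in pairs 91 and 1, windows of 6 libraries 91 higher, and the fit without 90 and 105 min 518 and 72. Leaving out 1 library gave 25 to 118 and 0 to 1. For 255 to 360 min against high phosphate (1154 and 252), the centrings gave 389 and 435, and 596 and 438. Leaving out 1 library gave 1094 to 1217 and 233 to 267. For 15 to 45 min against 60 to 120 min (150 and 111), the spline gave 8 and 2, the listing limit 48 and 25, the fit without 195 and 345 min 228 higher, and that without 90 and 105 min 2 and 0. Leaving out 1 library gave 8 to 402 and 1 to 349. The count of genes changing over time (1459) was 925 with median centring and 1141 to 1608 with 1 library left out.

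With 0.25 in place of 0.5 of the largest response, times were 6.33 min for the PHO regulon, 21.9 for ribosomal proteins, 8.40 for ribosome biogenesis, 8.80 for general stress, 46.5 for G1/S, 65.0 for histones, 4.66 for Hsf1 chaperones, 5.01 for sulfur assimilation and 5.14 for the unfolded protein response. With median centring they were 35.2 for ribosomal proteins, 15.0 for ribosome biogenesis, 278 for G1/S, 12.6 for histones and 314 for the unfolded protein response. With no running median, G1/S gave 54.6 and the unfolded protein response 51.8, and histones gave 165 without 90 and 105 min.

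Shifts of lists against other genes turned as follows. For 255 to 360 min against high phosphate, a mean of at least 6 left 2726 tested genes and the listing limit 5240, in place of 4613. List members and other genes in these 2 settings can thus differ from those of the main fit. Without 90 and 105 min, ribosome biogenesis stood at 0.165 between late and early windows, and ribosomal proteins at 0.135 between 15 to 45 and 60 to 120 min. Between 255 to 360 min and high phosphate, a mean of at least 6 gave 0.0784 for G1/S, 0.01001 for the mitochondrial ribosome and 0.17 for MATa markers, the listing limit gave -0.0548 for the unfolded protein response and 0.90 for hexose transporters, and the fit without 195 and 345 min gave 0.0262 for hexose transporters.

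PHO4 lost its call at 255 to 360 min against high phosphate with both centrings (0.754 and 0.838). Of named genes, 7 that had not passed turned. Values follow in the order centring on genes in all 25, then median centring, then without 90 and 105 min. Between late and early windows, PHO12 stood at -0.0512, -0.174 and -0.152, PHO86 at -0.0960, -0.219 and -0.0348, and SPL2 at -0.0914, -0.214 and -0.0331. PHO11 stood at -0.114 with median centring and -0.0337 without those libraries, and VTC2 at -0.0451 and -0.168 with the centrings. With the centrings, PHO4 stood at -0.0307 and -0.0428 at 15 to 120 min against high phosphate. VTC4 stood at -0.0539 and -0.0659 there, at -0.323 and -0.457 at 255 to 360 min, and at -0.00737 and -0.0437 between 15 to 45 and 60 to 120 min.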

Other observations

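The genes unlisted at 0 min were chosen after the data were seen, and the values of this part were not tested.

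There were 25 genes that were not listed at 0 min and were listed in all 8 libraries from 255 to 360 min. Against the listing limit of 10 reads at 0 min, the hexose transporter gene HXT5 was at least 31.9-fold higher (7.77 ± 0.58 log2 RPM, SD, n = 8), MOH1 at least 25.8-fold (7.46 ± 0.27) and URA10, an orotate phosphoribosyltransferase gene, at least 19.5-fold (7.06 ± 0.32). The phenylpyruvate decarboxylase gene ARO10 was at least 12.8-fold higher (6.45 ± 0.44), the proline permease gene PUT4 at least 11.8-fold (6.33 ± 0.24) and DAL80, a regulator of nitrogen catabolite genes, at least 10.8-fold (6.21 ± 0.46). In the other direction, 64 genes were listed at 0 min and in no library of that window, of which 9 had a value over 4 at 0 min.

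The sporulation regulators IME1 and IME2 were listed in 0 libraries, while NDT80 was listed in 25 at a mean of 5.92. The MATa pheromone genes MFA1 and MFA2 had means of 10.7 and 10.8 over 25 libraries, and the receptor gene STE2 a mean of 8.94.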
